A study of Mus musculus with 6 samples.

How the data were processed

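Expression was measured on Affymetrix mouse expression arrays (45101 probe sets) in total RNA from wild-type embryonic stem cells and from cells lacking both Gsk-3 genes (DKO), with 3 arrays per genotype. Per the labels' protocols the cells were grown without feeders on gelatin in medium with 15% serum and 1000 units/ml of leukaemia inhibitory factor, RNA was purified, and 25 ng were amplified and biotin-labelled as cDNA. Each array was assigned to its genotype and replicate number by its sample title.

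The deposited values are 1 intensity per probe set and array, given by the authors as whole numbers. Their scale is not stated. They were taken as linear because they are whole, at least 1 and reach 12861, and they were converted to log2 values here with no pseudocount. The submitters' processing notes name GCOS, GCRMA 2.14.1, R 2.8.0 and limma 2.16.5 without saying which step each served. The genome build is not given in the sources used here. Rounding to whole numbers makes low values coarse: the lower quartile of each array was an intensity of 4. No scanner files were used, and the table has no detection flags. The number of arrays limits the precision.

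Probe sets were named through the platform annotation and, by gene identifier, the current mouse RefSeq gene table (GRCm38.p6), which was used for names, chromosomes and the order of genes only. Of 45101 probe sets, 34958 had 1 gene, 932 had several and 9211 were unnamed; 64 probe sets were array controls; 34754 of the single-gene probe sets matched the RefSeq table. No gene was named from a probe set with several genes.

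A probe set was tested if its log2 value was at least 4 (intensity 16) on at least 3 of the 6 arrays, regardless of genotype, and if it was not an array control. This left 20841 probe sets, 18242 of them with 1 gene. DKO was compared with wild-type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, with statmod 1.5.0 installed), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Genes were counted over 1 probe set each, the tested probe set with the highest mean over all 6 arrays, which gave 10496 genes. Of these, 4593 had more than 1 tested probe set, and 0 had probe sets that passed in opposite directions. Values are means ± SD of log2 intensity, and SE is the moderated standard error of the difference. A group whose 3 arrays all lie under a log2 value of 4 has only a limit: the fold is then the bright group's mean against the mean of, per array, the higher of 4 and the measured value, and is written "at least". Log2 differences of such genes were used to rank and test them and enter the list means.

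The test, the filter, 40 gene lists and the rule for named genes were fixed before the data were examined. The lists hold imprinted genes by parental expression, signalling targets, pluripotency and lineage markers, DNA methylation genes, metabolic and stress pathways, cell cycle genes and markers of fibroblasts and blood, written from general knowledge. Of 841 members written, 831 were matched to a gene and 622 were tested. Some genes stand in several lists (Dnmt3a, Lefty1, Cldn6, Cdx2, Grb10, Igf2, Dppa3). Lists were tested with camera at a preset correlation of 0.01, adjusted over the 40 lists, beside camera with an estimated correlation and fry. The genes named are Gsk3a and Gsk3b; the 12 largest rises and 12 largest falls among genes that passed with all 3 DKO arrays beyond all 3 wild-type arrays, leaving out clone-named and predicted genes; a fixed set of pluripotency, Wnt, methylation and imprinted genes; from each list the up to 4 members that passed with the largest difference, or the 1 member with the largest difference where none passed; and every imprinted gene that passed. Where no member of a list passed, the list may be described by its list result alone, without printing that 1 member. Genes outside this rule, named after their values were seen, are Tnfrsf19, Dact1, Sall2, Grhl2 and Fgf15 and the neighbouring genes of the closing observations. T had no probe set named in the annotation.

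Arrays were compared before averaging. No 2 arrays were alike: at most 1.79% of the tested probe sets had exactly the same whole-number value on 2 arrays, and the SD of the log2 differences over tested probe sets was at least 0.54. The titles number the replicates 1 to 3 in both genotypes. Over tested probe sets, the deviations of same-numbered arrays from their genotype means correlated at 0.427, 0.354 and 0.595, each over 0.1. By the rule fixed for this check the numbers therefore pair the samples. Arrays of unlike number correlated at -0.488 to 0.113, and the highest, DKO replicate 2 with wild-type replicate 1, was also over 0.1. The labels do not say what a number stands for. The replicate number was left out of the model, as fixed beforehand, and entered as a block in an alternative.

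The procedure was tested on simulated data for this comparison, with the measured means and moderated SDs of 20841 probe sets, 3 arrays against 3 and 5 runs. It called 14.8% of probe sets changed by 1 log2 unit, 92.9% of those changed by 2 and 100% of those changed by 4, and 7.46% of its calls were false. With lists of 20 genes among 10496, a list shifted by 0.5 log2 units was called in 20 of 20 runs and 0 of 780 unchanged lists were called. Genes varied independently in the simulated data, so this does not test the list calls where genes are correlated.

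Alternatives were no filter and a stricter filter at a log2 value of 6, quantile normalization, median centring, a trended and robust prior, array weights, the replicate block, a test against a log2 difference of 1 (treat), the linear model without moderation, the mean of all probe sets of a gene and the omission of each array in turn. The fits that each left out an array did not have the replicate number in the model. The hybridisation batch as a block and the use of replicates 1 and 2 alone were added after seeing the data. Figures were drawn with matplotlib 3.10.9.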

Results

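Gene expression was measured in mouse embryonic stem cells of 2 genotypes, wild-type cells and cells lacking both genes of glycogen synthase kinase-3 (Gsk-3a-/-; Gsk-3b-/-, called DKO below). Gsk-3 is a serine/threonine kinase that acts downstream of insulin and PI3K signalling and, in the Wnt pathway, marks beta-catenin for degradation. Total RNA from 3 samples per genotype was hybridised to 6 Affymetrix mouse expression arrays with 45101 probe sets each. The cells were grown without feeders, on gelatin, in medium with 15% serum and 1000 units/ml of leukaemia inhibitory factor. The arrays had median intensities of 10 to 11 and upper quartiles of 130 to 140, and their number limits the precision of every value. After removal of dim and control probe sets, 20841 probe sets were tested, and 10496 genes were each represented by 1 of them. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The sample titles give only genotype and replicate number. Differences between cell lines that do not come from the loss of Gsk-3 therefore cannot be told apart from those that do.

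The series asks which transcripts differ between the genotypes, and its title adds PI3K signalling through Gsk-3 and the DNA methylation of imprinted loci. The targeted genes were examined in each sample before the other genes. The probe set of Gsk3a had a log2 intensity of 6.77 ± 0.63 in DKO and 8.15 ± 0.44 in wild-type cells (SD, n = 3). Every DKO array lay below every wild-type array, at 7.18, 7.08 and 6.04 against 8.65, 7.90 and 7.90, but the difference of -1.38 (SE 0.36) did not pass the threshold (adjusted p = 0.0942; 0.106 to 0.208 over the 6 fits that each left out an array). With the replicate number as a block it passed (adjusted p = 0.00646), and with the hybridisation batch described in the next paragraph as a block it also passed (adjusted p = 0.0223). Gsk3b had 5 tested probe sets, and by limma 0 of them passed. Their log2 differences ran from -0.71 to -0.02, and the brightest read 10.40 ± 0.23 in DKO against 10.61 ± 0.08 in wild-type cells (adjusted p = 0.832). The position of these probe sets relative to the deleted parts of the genes was not known here, and a probe set outside a deleted part does not check the labels.

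**Figure D1:**
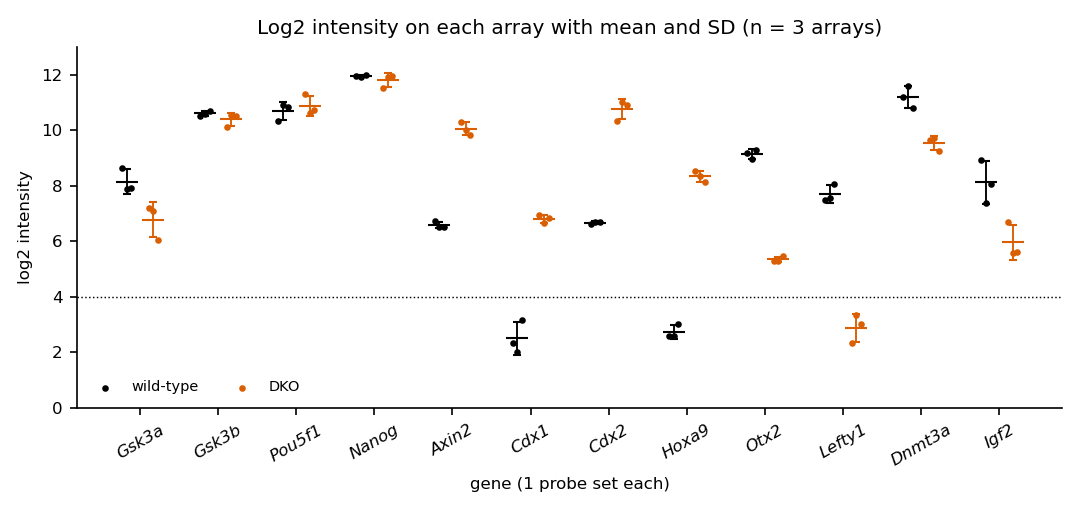
Log2 intensity of 12 genes, 1 probe set each, on the wild-type arrays (black) and the DKO arrays (orange); points are single arrays, horizontal bars the mean of 3 arrays and whiskers the SD. The dotted line is the filter at a log2 intensity of 4. Axin2, Cdx1, Cdx2 and Hoxa9 lie higher on every DKO array, Otx2, Lefty1, Dnmt3a and Igf2 lie lower, and the points of Gsk3b, Pou5f1 and Nanog overlap or nearly touch.

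The arrays of replicate 3 stood apart in both genotypes. Bacterial and phage spike-in control probe sets (9 per array) had a mean log2 signal of 9.50 on DKO replicate 3 and 9.91 on wild-type replicate 3, and between 1.73 and 1.85 on the other 4 arrays, so replicate 3 was treated as a separate hybridisation batch that holds both genotypes. Signal at the 3' end over the 5' end of 3 control transcripts, a sign of RNA length, averaged 2.20 ± 0.32 log2 units in DKO and 1.98 ± 0.33 in wild-type cells (SD, n = 3). It was higher in DKO in each of the 3 same-numbered pairs, by 0.028, 0.439 and 0.192, so a difference in RNA length between the genotypes was not excluded.

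DKO cells differed from wild-type cells in many genes, by large factors. Homeobox genes of the posterior embryo (Nkx1-2, Hoxa9, Cdx1, Cdx2), the Wnt targets Axin2 and Sp5 and the betaine pathway genes Bhmt, Bhmt2 and Dmgdh rose. Genes of the primed epiblast (Otx2, Pou3f1, Fgf5, Lefty1), the guanylate-binding protein genes Gbp2, Gbp2b and Gbp3 and several imprinted genes (Phlda2, Cdkn1c, Nnat) fell. The core pluripotency genes Pou5f1, Sox2 and Nanog stayed within 0.21 log2 units of wild-type. In all, 434 of 10496 genes passed an adjusted p of 0.05, 172 higher and 262 lower in DKO. Of these, 198 had a fitted difference of at least 4-fold. Counts by fold size use fitted differences throughout, also for genes dim in 1 genotype, whose fold has only a lower limit.

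Counted by probe set, 675 of 20841 passed, 273 higher and 402 lower. Each had a fitted difference of at least 2-fold, with a smallest absolute log2 difference of 1.01 and a median of 1.88. The lower limit can be smaller where a genotype was dim, as for Tex13b (at least 1.12-fold). The arrays of the genotypes did not overlap in 3490 probe sets (16.8%, where chance gives 10%), among them all 675. With the replicate number as a block the counts were 1995 probe sets (899 higher, 1096 lower, 1398 at least 2-fold) and 1123 genes. All 675 probe sets and 434 genes were among them. The block is balanced, so the log2 differences and their directions could not change. With the hybridisation batch as a block, an alternative chosen after seeing the data, 1117 probe sets and 687 genes passed. Within the batch of replicates 1 and 2 alone, 440 probe sets passed, 384 of them among the 675. The count fell to 290 without DKO replicate 1, 381 without DKO replicate 2 and 319 without wild-type replicate 2.

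**Figure D2:**
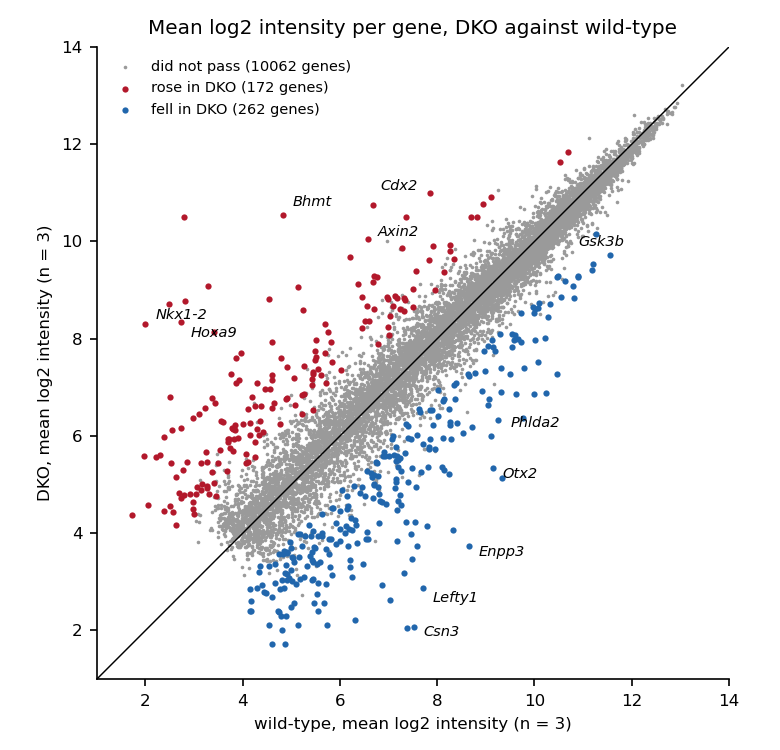
Mean log2 intensity of each of 10496 genes on the 3 wild-type arrays (horizontal axis) and the 3 DKO arrays (vertical axis), 1 point per gene; the line marks equal values. The 172 genes that rose in DKO are red, the 262 that fell are blue and those that did not pass are grey, with 11 genes named.

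The largest rises included genes with no signal above the filter in wild-type cells. For genes at log2 values under 4 on all 3 arrays of a genotype, the fold is given as a lower limit against the filter. Nkx1-2, a homeobox transcription factor, read 8.31 ± 0.35 in DKO, at least 19.8-fold above wild-type. Ct55, a cancer/testis antigen, was at least 26.3-fold higher and Pglyrp1, a peptidoglycan recognition protein, at least 34-fold higher. Hoxa9 read 8.34 ± 0.20 in DKO and was at least 20.3-fold higher. Dmgdh (dimethylglycine dehydrogenase) and Bhmt2 were at least 27.6-fold and 17.5-fold higher, and Bhmt (betaine-homocysteine methyltransferase) rose from 4.84 ± 0.78 to 10.54 ± 0.27, a log2 difference of 5.70 (adjusted p = 0.000151). Crxos rose by 3.92 and Flvcr2, a membrane transporter, by 3.74 on the log2 scale (3.65 with the wild-type arrays under the filter set to it). Clone-named and predicted genes are left out of this ranking, and some rose more. Among the other genes, the adjusted p-values of the 12 rises largest by fitted difference lay between 1.79e-05 (Nkx1-2) and 0.000794 (Sp5).

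The falls largest by fitted difference included Csn3 (kappa-casein) and Gbp2b, at least 11.5-fold and 10.5-fold lower in DKO; where the DKO arrays were dim, the order of these genes is not known. Csn3 varied among the wild-type arrays (7.52 ± 1.85, adjusted p = 0.00549) and did not pass without DKO replicate 1 (highest adjusted p over the 6 fits that leave out an array, 0.0693). Enpp3, an ectonucleotidase, was at least 25.3-fold lower (8.66 ± 0.37 in wild-type), and all 3 of its tested probe sets passed. Lefty1, an extracellular inhibitor of Nodal, was at least 13.1-fold lower. Gbp2 and Gbp3, interferon-inducible GTPases like Gbp2b, were at least 10-fold and 4.98-fold lower. Fndc3c1 and Crmp1, the latter a collapsin response mediator of neurons, were at least 8.19-fold and 7.32-fold lower. The log2 differences of Tnfsf11 (RANK ligand), Spink1, a trypsin inhibitor, Myrf, a membrane-bound transcription factor, and Car3, a carbonic anhydrase, were -4.25, -4.20, -4.01 and -3.84. Some DKO arrays of Tnfsf11, Myrf and Car3 lay under the filter, and with these set to it the differences were -4.09, -3.45 and -3.50. Probe sequences were not used here, so cross-hybridisation between the Gbp genes, or between Bhmt and Bhmt2, was not examined.

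Targets of Wnt/beta-catenin signalling were higher in DKO on balance. Of 25 tested members of this list 5 rose, 2 fell and 18 did not pass. Adjusted over the list alone, 8 rose and 3 fell. Axin2, a negative regulator and direct target of the pathway, rose from 6.58 ± 0.12 to 10.06 ± 0.23 (difference 3.47, SE 0.24, adjusted p = 0.000151). Cdx2 rose by 4.09, Sp5 by 4.28 and Cdx1 at least 7-fold, and Tnfrsf19, named after its values were seen, rose by 1.24. Lef1, a transcription factor that binds beta-catenin, fell by 1.21 (adjusted p = 0.0287) and Dact1, also named afterwards, fell by 1.34. The fall of Lef1 passed in only 1 of the 6 fits that left out an array, the fit without wild-type replicate 1. Over these 6 unpaired fits its adjusted p ran from 0.0362 to 0.148. With all arrays and the replicate number as a block it was 0.00523. Ccnd1 (difference 0.86, adjusted p = 0.288), Myc (0.05, adjusted p = 0.983) and Ctnnb1, which encodes beta-catenin (-0.13, adjusted p = 0.916), did not pass, and T was not analysed here. The list had a mean log2 difference of 0.90 (camera, adjusted p = 0.000357), but adjusted p = 0.178 with an estimated correlation. The mean was 0.88 over replicates 1 and 2 and 0.94 in replicate 3, with an adjusted p of 0.000556 with the batch as a block. Of 9 tested Hox genes, Hoxa9 and Hoxa10 (difference 2.58, adjusted p = 0.00174) rose and 7 did not pass; adjusted over the list alone, 6 rose and 1 fell, as with the replicate number as a block. The Hox list had a mean of 1.57 (adjusted p = 0.000357; adjusted p = 0.343 with an estimated correlation), 1.48 over replicates 1 and 2 and 1.76 in replicate 3.

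Genes of the primed epiblast, the state that follows naive pluripotency around implantation, formed the list with the lowest adjusted p. Of 17 tested members 9 fell, none rose and 8 did not pass, and 12 fell when adjusted over the list alone. Otx2, a homeobox gene of the early epiblast, fell from 9.14 ± 0.18 to 5.34 ± 0.10 (difference -3.80, SE 0.23, adjusted p = 8.71e-05). Pou3f1 (Oct6) fell by 3.12, Fgf5 was at least 2.89-fold lower and Lefty1 at least 13.1-fold lower. Cldn6 (-2.40), Sall2, Grhl2, Fgf15 and Dnmt3a also fell; Sall2, Grhl2 and Fgf15 were named after their values were seen. Cldn6 did not pass without DKO replicate 1 (adjusted p = 0.0683). The brightest probe set of Dnmt3a did not pass without DKO replicate 1 or wild-type replicate 2 (highest adjusted p = 0.0709). The list had a median of -1.67, or -1.48 with dim members at their limit, and a mean of -1.77 (camera, adjusted p = 9.67e-15). The mean was -1.76 over replicates 1 and 2 and -1.78 in replicate 3 (adjusted p = 5.36e-13 with the batch as a block). This was the only one of the 40 lists that also passed with an estimated correlation (adjusted p = 0.0361), and with the replicate block and an estimated correlation it did not (adjusted p = 0.494).

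Pou5f1 read 10.88 ± 0.37 in DKO and 10.69 ± 0.33 in wild-type cells, Sox2 11.63 ± 0.33 and 11.84 ± 0.0031 and Nanog 11.81 ± 0.24 and 11.95 ± 0.04, with adjusted p-values of 0.887, 0.845 and 0.895. By limma 0 of the 21 tested core pluripotency genes and 0 of the 20 naive pluripotency genes passed, also adjusted over the list alone. At an unadjusted p under 0.05 there were 3 and 2, the linear model without moderation called 0 and 0, and the replicate block called 2 and 1. The member of both lists with the largest difference was Dppa3, a maternal factor that protects DNA methylation in the zygote, at 4.39 ± 0.69 against 5.73 ± 0.64 (adjusted p = 0.171; 0.00297 with the block). The lists as wholes had adjusted p-values of 0.0833 (core, mean -0.24; 0.0174 to 0.449 over 18 alternatives, 4 of which passed, fry among them at 0.0323) and 0.226 (naive, mean 0.13; 0.0835 to 0.736).

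**Figure D3:**
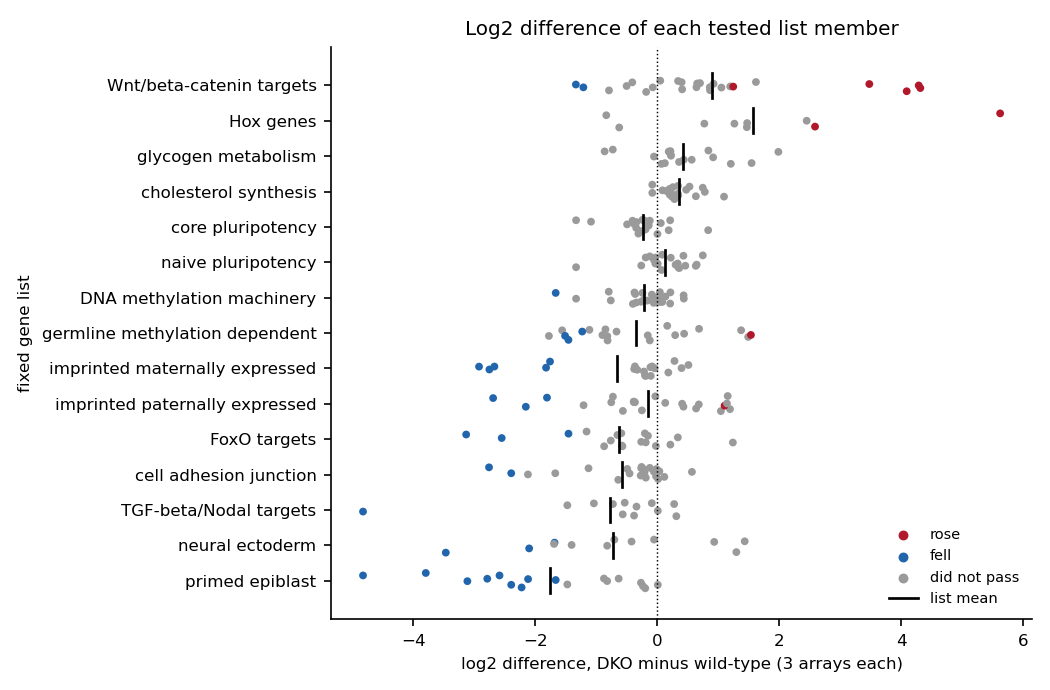
Log2 difference between DKO and wild-type (3 arrays each) of every tested member of 15 gene lists; each point is a gene, red where it rose, blue where it fell and grey where it did not pass, and the black bar is the mean of the list. The primed epiblast list has a mean of -1.77 and the Wnt/beta-catenin list of 0.90.

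More of the imprinted genes that passed fell than rose, as over all genes, where 262 of 434 fell. Of the maternally and the paternally expressed lists, only the maternally expressed one passed as a whole. Among 19 tested maternally expressed genes 5 fell, 0 rose and 14 did not pass, with the same counts adjusted over the list alone. Phlda2 fell from 9.26 ± 0.25 to 6.33 ± 0.70 (difference -2.93, SE 0.36, adjusted p = 0.00256). Cdkn1c, an inhibitor of cyclin-dependent kinases and next to Phlda2 in the order of tested genes, was at least 3.26-fold lower (adjusted p = 0.00211). Atp10a, a phospholipid flippase, fell by 2.67, Grb10, an adaptor that restrains insulin signalling, fell by 1.83, and Calcr, the calcitonin receptor, was at least 1.88-fold lower. The list had a mean log2 difference of -0.67 and a median of -0.20 (camera, adjusted p = 0.00462; adjusted p = 0.216 with an estimated correlation). Its mean was -0.67 over replicates 1 and 2 and -0.66 in replicate 3 (adjusted p = 0.00553 with the batch as a block). Igf2r (difference -0.19, adjusted p = 0.853) did not pass. Meg3 had 7 tested probe sets, all below 0, of which 1 passed; the brightest differed by -0.33 (adjusted p = 0.683).

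Of 22 tested paternally expressed genes 1 rose, 3 fell and 18 did not pass; adjusted over the list alone, 2 rose and 3 fell, and with the replicate block 5 rose and 5 fell. Nnat, a neuronal membrane protein, fell from 7.18 ± 0.09 to 4.49 ± 0.48 (adjusted p = 0.00138). Peg3, a zinc-finger gene, fell by 1.81, and all 3 of its probe sets passed. Igf2, a fetal growth factor, fell from 8.12 ± 0.77 to 5.96 ± 0.63 (adjusted p = 0.0324) and Plagl1, a zinc-finger transcription factor, rose by 1.10 (adjusted p = 0.0405), the smallest rise of its 3 probe sets, which rose by 1.10 to 3.49 and all passed. The list as a whole did not pass (mean -0.16, adjusted p = 0.536). Dlk1 (1.15, adjusted p = 0.442), Mest (-1.21, 0.193) and Snrpn (-0.76, 0.253) passed only with the replicate block (adjusted p = 0.0327, 0.0129 and 0.0438), and Mest also with the batch as a block and without wild-type replicate 1 (adjusted p = 0.0489). Peg10 read 11.56 ± 0.89 against 11.13 ± 0.41 (adjusted p = 0.81). H19 shares its probe set in the annotation with a microRNA gene and is not named by a value. Single arrays mattered in the 6 fits that left out an array, which did not pair the samples by number. Among these, Igf2 passed only without wild-type replicate 2 and Calcr only without DKO replicate 2 or wild-type replicate 3. Plagl1 passed in none, and the highest adjusted p-values were 0.137, 0.158 and 0.169. With all arrays and the replicate number as a block, limma gave adjusted p = 0.000292, 0.00251 and 0.01 for Igf2, Calcr and Plagl1. For Plagl1 all of these fits were read on its brightest probe set alone.

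**Figure D4:**
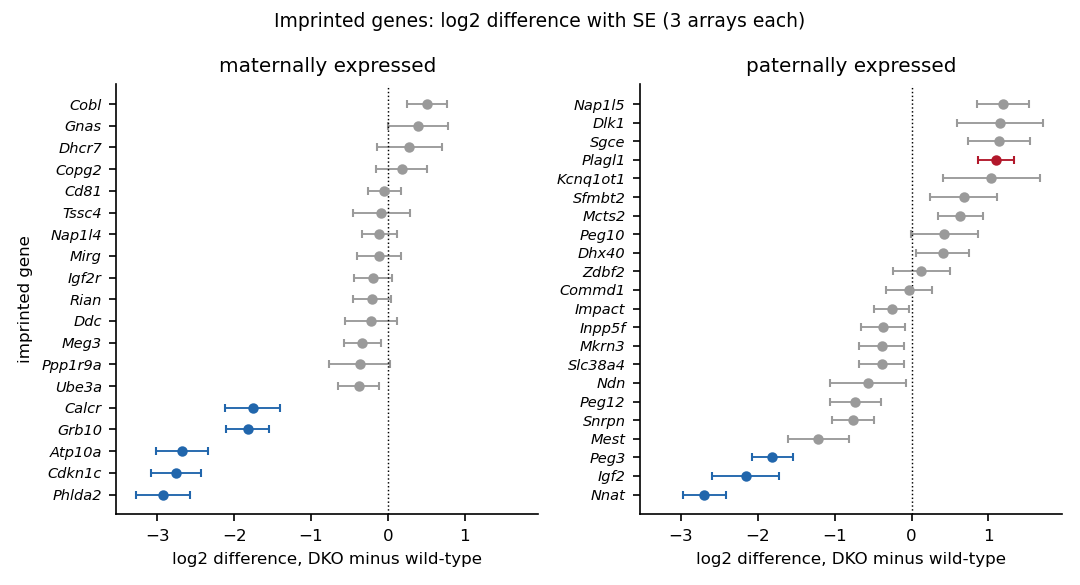
Log2 difference between DKO and wild-type with its SE (3 arrays each) for 19 maternally expressed and 22 paternally expressed imprinted genes; blue genes fell, the red gene rose and grey genes did not pass. Phlda2 has the lowest plotted value among maternally expressed genes at -2.93, and Nnat among paternally expressed genes at -2.69.

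Among 26 tested genes of the DNA methylation machinery 1 fell, 0 rose and 25 did not pass, also adjusted over the list alone, and with the replicate block 2 fell (Dnmt3a and Dppa3). Dnmt3a, a de novo DNA methyltransferase, fell from 11.20 ± 0.40 to 9.53 ± 0.26 (difference -1.67, SE 0.28, adjusted p = 0.0142). All 5 of its tested probe sets were below 0, between -2.62 and -0.90, and 2 passed. On the brightest probe set, the only one read in these fits, the call was lost without DKO replicate 1 or without wild-type replicate 2 (highest adjusted p = 0.0709). With the replicate number as a block this probe set had an adjusted p of 0.000923 by limma. The other probe set that passed differed by -2.62 (adjusted p = 0.0016). Dnmt3b (-0.27, adjusted p = 0.753), Dnmt3l (-0.35, 0.63), the maintenance enzyme Dnmt1 (0.05, 0.975) and its partner Uhrf1 (-0.05, 0.973) did not pass. The list did not pass by camera (adjusted p = 0.192) and was lower by fry (adjusted p = 0.0323), which does not compare a list with other genes; 17 of 18 alternatives did not pass. Of 20 tested germline genes whose promoters are methylated in somatic cells, 1 rose (Tex13b, at least 1.12-fold), 3 fell (Slc25a31 by 1.51, Mael by 1.46, Taf7l by 1.23) and 16 did not pass; adjusted over the list alone, 3 rose and 9 fell, and with the replicate block 3 rose and 8 fell. Without single arrays, in fits that did not pair the samples, these calls were often lost. Mael passed only without DKO replicate 2 and Tex13b only without wild-type replicate 1. Taf7l passed only without DKO replicate 3 or wild-type replicate 3. Slc25a31 did not pass without DKO replicate 1, DKO replicate 2 or wild-type replicate 2. The highest adjusted p-values were 0.213, 0.195, 0.127 and 0.0821. With all arrays and the replicate block, limma gave 0.00589, 0.00448, 0.00829 and 0.00317 in the same order. The list moved down (mean -0.35, adjusted p = 0.0383; adjusted p = 0.457 with an estimated correlation). Its call held in 10 of 18 alternatives and was lost without the filter, with the replicate block (adjusted p = 0.0536), and without DKO replicate 1, DKO replicate 3, wild-type replicate 1 or wild-type replicate 2 (highest adjusted p = 0.102).

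FoxO targets, which insulin signalling represses, moved down (18 tested, 0 rose, 3 fell, 15 did not pass; adjusted over the list alone, 1 rose and 6 fell; with the replicate block, 1 and 5; mean -0.63, adjusted p = 0.000735; adjusted p = 0.191 with an estimated correlation). The members that fell were Bcl2l11 (Bim, a mediator of apoptosis, -2.55), Ccng2 (cyclin G2, -1.46) and Fbxo32 (atrogin-1, a ubiquitin ligase subunit), at least 2.92-fold lower. Ccng2 did not pass without DKO replicate 1, DKO replicate 2 or wild-type replicate 2 (highest adjusted p = 0.0882), nor Fbxo32 without DKO replicate 1 (adjusted p = 0.0505). Of 27 tested PI3K and insulin pathway genes, Grb10 and Igf2 fell and 25 did not pass (1 rose and 3 fell adjusted over the list alone; adjusted p = 0.862, with a mean of -0.02 and a median of 0.11, which differ in sign). By limma 0 of 17 tested members of the glycogen metabolism list passed, also adjusted over the list alone, with 6 at an unadjusted p under 0.05, 0 by the model without moderation and 5 with the replicate block (4 rose, 1 fell). Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1, read 5.10 ± 1.03 against 3.11 ± 0.71 (adjusted p = 0.099; 0.00134 with the replicate block and 0.044 without DKO replicate 2). This list shifted up (mean 0.42, adjusted p = 0.0416; adjusted p = 0.5 with an estimated correlation), but kept its call in only 9 of 18 alternatives and lost it also without the filter, with the stricter filter, with array weights and with the mean of all probe sets of a gene. The cholesterol synthesis list also shifted up and kept its call in 13 of 18 alternatives (20 tested, 0 passed by limma, 1 rose adjusted over the list alone, 3 at an unadjusted p under 0.05, 0 by the model without moderation, 2 with the replicate block; mean 0.35, adjusted p = 0.0129; adjusted p = 0.636 with an estimated correlation), where Tm7sf2, a sterol reductase, differed by 1.09 (adjusted p = 0.0508; 0.00809 with the replicate block). Both calls were lost without DKO replicate 1 or wild-type replicate 3, the glycogen call also without wild-type replicate 2 and the cholesterol call also without DKO replicate 2 (highest adjusted p = 0.164 and 0.274).

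Single lineage markers moved in different directions. Of the neural ectoderm, trophoblast, mesendoderm and primitive endoderm lists, only neural ectoderm passed in the main fit. Of 12 tested neural ectoderm genes 3 fell, 0 rose and 9 did not pass (2 rose and 5 fell adjusted over the list alone; 1 and 6 with the replicate block), and the list shifted down (mean -0.73, adjusted p = 0.0129; adjusted p = 0.23 with an estimated correlation), though not with the stricter filter. Pax6, a homeobox gene of the eye and neural tube, fell (-3.47), as did Neurod1 (-2.10) and Ncam1 (-1.69); Neurod1 did not pass without DKO replicate 1, DKO replicate 2 or wild-type replicate 2 (highest adjusted p = 0.113). With DKO arrays under the filter set to it, Pax6 and Neurod1 differed by -3.24 and -1.88. Of 13 tested trophoblast genes Cdx2 and Tfap2a rose (4.09 and 3.46), 11 did not pass and the list did not pass (adjusted p = 0.289; 3 rose adjusted over the list alone), except without DKO replicate 2 (adjusted p = 0.0399) or wild-type replicate 1 (adjusted p = 0.0441). Among 12 mesendoderm genes Actc1 (cardiac actin) was at least 1.74-fold lower and 11 did not pass (2 rose and 2 fell adjusted over the list alone, and with the replicate block; adjusted p = 0.0718, and 0.0247 without wild-type replicate 2 and 0.00782 with the stricter filter). Of 21 tested primitive endoderm genes 0 passed by limma on their brightest probe set, also adjusted over the list alone, 6 had an unadjusted p under 0.05, the model without moderation called 0 and the replicate block 3. The other probe set of Hnf4a passed (difference 3.10), while the brightest (2.61) read 9.84 ± 0.31 against 7.23 ± 1.87 (adjusted p = 0.134; 0.0255 with the replicate block, 0.042 without wild-type replicate 1 and 0.0366 without wild-type replicate 3). The list mean was -0.30 over replicates 1 and 2 and 1.37 in replicate 3, opposite in sign between the batches (adjusted p = 0.394, and 0.0441 without wild-type replicate 1). Fibroblast genes, which a carry-over of feeder cells would bring, did not pass as a list (12 tested, 1 fell, 11 did not pass, 3 fell adjusted over the list alone; mean -0.32 and median 0.18, which differ in sign; adjusted p = 0.631), and Tagln, an actin-binding protein, fell among them (-3.64, or -3.58 with the DKO array under the filter set to it). Nodal and TGF-beta targets shifted down (12 tested, 1 fell, 11 did not pass, 3 fell adjusted over the list alone; adjusted p = 0.0129; adjusted p = 0.23 with an estimated correlation), with Lefty1 as the member that fell. Cell adhesion genes shifted down as well (22 tested, 2 fell, 20 did not pass, 3 fell adjusted over the list alone, 5 with the replicate block; adjusted p = 0.0129; adjusted p = 0.449 with an estimated correlation), with falls of Esrp1, an epithelial splicing regulator (-2.76), and Cldn6 (-2.40, adjusted p = 0.0683 without DKO replicate 1).

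In all, 11 of the 40 lists passed with the preset correlation, 4 upward and 7 downward, and 1 passed with an estimated correlation, which for each of the 11 gave the highest adjusted p over 18 alternatives. Fry, which does not compare a list with other genes, called 9: it left out cell adhesion (adjusted p = 0.173), germline (0.154), glycogen (0.173) and cholesterol (0.347) and added core pluripotency and DNA methylation machinery (0.0323 each). The cell cycle lists (adjusted p = 0.311 for G2/M and 0.862 for S phase genes), Myc targets (0.676), glycolysis (0.676), oxidative phosphorylation (0.676) and the p53 (0.503), hypoxia (0.676) and unfolded protein response (0.394) lists did not pass. Nor did the targets of BMP (0.753), FGF/ERK (0.968) and LIF/STAT3 signalling (0.676) and the interferon list (0.822). Of the means and medians of these lists, those of glycolysis (0.12 and -0.04), FGF/ERK (0.04 and -0.03) and LIF/STAT3 (-0.17 and 0.0047) differed in sign. The G2/M list passed only without the filter (adjusted p = 0.0387). Fatty acid synthesis (adjusted p = 0.171; 0.0404 without DKO replicate 3 and 0.0306 with the mean of all probe sets of a gene), the ATF4 response (0.58), oxidative stress (0.987; mean 0.047, median -0.0060), heat shock and immediate early genes (0.179), blood (0.354), Y-linked (0.429) and X inactivation genes (0.693; mean -0.12, median 0.028) did not pass either. The two-cell-like list (6 tested) had an adjusted p of 0.0517 and passed in 7 of 18 alternatives, among them the replicate block (0.0158), the batch as a block (0.0321) and the fits without DKO replicate 2, wild-type replicate 1 or wild-type replicate 3 (lowest 0.00641). Single members of these lists passed: the log2 differences of Id1 (BMP), Icam1 (LIF/STAT3), Adm (hypoxia) and Zfp36 (immediate early) were -1.19, -1.37, -2.17 and -1.87, Cish was at least 2.03-fold lower (LIF/STAT3), and in the interferon list Oas1a rose by 2.83 while Psmb8 was at least 1.35-fold lower. Icam1 passed in none of the 6 unpaired fits that left out an array, Cish only without wild-type replicate 2 and Id1 only without DKO replicate 3. Adm and Oas1a passed in all but those without DKO replicate 2 and DKO replicate 1, respectively. The highest adjusted p-values were 0.156 for Icam1, 0.14 for Cish, 0.167 for Id1, 0.0585 for Adm and 0.053 for Oas1a. With all arrays and the replicate number as a block, limma gave 0.00237, 0.00364, 0.00853, 0.00055 and 0.000135 in the same order.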

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

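The tests on the replicate 3 arrays and on Gsk3b were chosen only after these results were seen.

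Spike-in control probe sets, which the comparison of genotypes does not use, carried signal on the replicate 3 arrays only. Their mean log2 value was 9.50 on DKO replicate 3 and 9.91 on wild-type replicate 3, against at most 1.85 on the other 4 arrays. The gap was 18.65 times the larger range within either set of arrays, which is what a separate hybridisation of replicate 3 would give, with spike-in RNA added on that occasion only. Signal at the 3' end over the 5' end of control transcripts also set replicate 3 apart, by 2.41 times the mean range within a replicate number, so a difference in RNA length stays open beside it. Neither explanation extends to replicates 1 and 2. Their difference in DKO correlated with that in wild-type cells at 0.3 over tested probe sets, although none of these 4 arrays carried spike-in signal, and their 3' to 5' signal differed by only 0.392 times the range within these numbers. Arrays without spike-in signal need not share 1 hybridisation, so replicates 1 and 2 may also have been hybridised apart. What a replicate number stands for is not in the labels, and a shared culture day, RNA preparation or hybridisation remains untested. Both batches hold both genotypes.

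No Gsk3b probe set passed as lower in DKO, although the labels name the gene as disrupted. A single mislabelled DKO array is argued against. Over probe sets called without it, the DKO array closest to wild-type still lay at 0.921 of the other DKO arrays' distance from the wild-type mean. A single such array would also not account for Gsk3b, whose brightest probe set read 10.13, 10.55 and 10.52 on the 3 DKO arrays. The check compares the DKO arrays with each other, so it cannot test a label that is wrong on all 3. Wild-type cells mixed into DKO are argued against as well, since 55 tested probe sets lay more than 4-fold below the lowest wild-type value on all 3 DKO arrays, and Gsk3b stood at 86.7% of its wild-type level. Probe sets outside the deleted part could give the same picture: 0 of 5 tested Gsk3b probe sets passed as lower, and without probe positions this cannot be told apart from an RNA that the mutation leaves in place.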

How the results depend on the processing

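The batch block and the use of replicates 1 and 2 alone were tests chosen only after the data were seen. Counts of probe sets, of probe sets changed at least 2-fold by fitted difference and of genes were 675, 675 and 434. Without the filter 273 probe sets changed at least 2-fold and 247 genes passed; the 495 probe sets that passed at any size shared 238 with the 675, and 48.5% of them fell, against 59.6%. The stricter filter gave 373, 373 and 253, with fewer probe sets tested. The replicate block, that is the pairing by number, gave 1995, 1398 and 1123; treat 131, 131 and 92; the linear model without moderation 31, 30 and 22; the batch block 1117, 1036 and 687; and replicates 1 and 2 alone 440 and 440 probe sets. Leaving out each array in turn gave 290 to 604 probe sets, 290 to 604 changed at least 2-fold and 184 to 374 genes, lowest without DKO replicate 1. Fewer arrays or a higher bar are part of the construction of several of these; otherwise the cause was not tested. No call shared with these settings changed sign. Several settings leave the log2 difference of a probe set as it was: both filters, the trended prior, both blocks, treat and the model without moderation. In those no sign could change, which also holds for the fits of named genes below. Quantile normalization, median centring, the trended prior and array weights kept the counts within 1.5 times. With an estimated correlation 1 list passed in place of 11, fry called 9, and leaving out arrays gave 8 to 13. Gsk3a passed with the replicate block and the batch block, both balanced, so that its log2 difference of -1.38 could not change there; leaving out arrays gave -1.59 to -1.02, none of which passed. Over the named genes, 1435 of 1650 alternative fits kept side and direction, 185 lost a call, 30 gained it and 0 reversed; over the lists these were 667 of 718, 31, 20 and 0. Under the replicate block the germline list was lost, the two-cell-like list gained (adjusted p = 0.0158; lowest 0.00641 and highest 0.457 over its alternatives), and no named gene lost its call. Values near the floor of the arrays, where rounding is coarse, limit what the dim genes can show.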

Other observations

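Tests of replicate splits, of neighbouring genes and of chromosomes were set out before their results were seen, although Bhmt, Bhmt2 and Dmgdh had been seen among the largest rises.

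Some genes that changed in DKO lay side by side in the order of the tested genes along the chromosomes. Genes that were not tested can lie between such neighbours, and distances were not computed. The betaine genes Bhmt, Bhmt2 and Dmgdh, which follow each other in this order, rose: Bhmt by 5.70 on the log2 scale, Bhmt2 at least 17.5-fold and Dmgdh at least 27.6-fold. The guanylate-binding protein genes Gbp7, Gbp3, Gbp2b and Gbp2 form a run that fell, with Gbp7 at least 4.59-fold lower. Nkx1-2 rose together with its neighbours Oat (1.67) and Lhpp (2.39), and Ahsg rose with Fetub, Btla with Cd200 and Tbx18 with Nt5e. Falling neighbours included Myrf and Syt7, Fndc3c1 and Taf9b, Galnt7 and Mfap3l, and the imprinted pair Cdkn1c and Phlda2. Lefty1 fell beside Tmem63a (at least 2.67-fold lower). The pairs outside the named-gene rule were chosen after their values were seen.

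A hypothesis from this is that part of the change followed position in the genome. Among 10470 placed tested genes, 46 adjacent pairs passed in the same direction. The mean was 9.21 and the maximum 24 in 10000 random placements of the calls (permutation p = 0.0001, the smallest they can give). Cross-hybridisation among similar neighbours may add pairs, but leaving out pairs that share a symbol stem still left 38, against a mean of 8.94 and a maximum of 23 (permutation p = 0.0001, again the smallest). Adjacent genes of like expression and adjacent genes that share a transcript or an enhancer were not told apart, so the cause stays open.

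A gain or loss of a chromosome copy in either line was looked for through the median log2 difference per chromosome. The largest was 0.0807, on chromosome 7 of GRCm38.p6 (772 genes), below the 0.3 set as the limit, and no chromosome passed (camera, adjusted p = 0.872).

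The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 675 probe sets, all at least 2-fold by fitted difference, and 434 genes. The highest other split gave 1 probe set, 1 at least 2-fold, and 0 genes, so that 1 of the 10 splits reached the real counts. The 3 other splits that, like the real one, part all same-numbered arrays gave 0 probe sets with and without the replicate block, against 1995 with it for the real split. Every other split puts both genotypes into each group, so any difference between the genotypes adds to the spread and holds these counts down. They are therefore not a rate of false calls for the real split.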
